A study of Oryza sativa with 14 samples.

How the data were processed

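RNA from seedlings of rice (Oryza sativa, cultivar Kitaake) was measured in wild type (WT) plants and in osnat10, a line named after N-acetyltransferase 10. Per the labels' protocols, plants grew in Yoshida nutrient solution with 10 h of light and 14 h of darkness a day, and libraries were read as single-end reads of 150 bp. The labels list 14 libraries. RNA-seq has 3 biological replicates of WT and 3 of osnat10. The acRIP-seq assay, in which fragmented RNA is pulled down with an antibody against N4-acetylcytidine (ac4C), has 8 libraries, 2 each of pull-down and input in either genotype. The acRIP-seq libraries were not analysed here.

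Per the file headers, the authors deposited a table of RPKM (reads scaled by gene length and library total) for 38978 genes in the 6 RNA-seq libraries. Genes carry their locus identifiers, symbols and descriptions in that table. The submitters' processing notes name STAR 2.5.3a, DESeq2, deepTools and the genome build IRGSP-1.0, with no role or order, and the read counter and annotation release are not given in the sources used here. Whether the RNA-seq counting used the strand is likewise not given, so reads of overlapping or antisense genes cannot be assigned with certainty. The same holds for near-identical gene copies, which are frequent among histone, Rubisco small subunit, light-harvesting and ribosomal protein genes.

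The second table holds the authors' own comparison of osnat10 with WT for 32190 genes, with the column names of DESeq2. Its mean normalised signal per gene (a mean of size-factor-scaled counts) was computed by the authors over all libraries. Its log2 fold change with standard error was likewise deposited by the authors, with a positive value for higher expression in osnat10, as the sign of the difference in mean RPKM showed for all 1681 genes with an adjusted p under 0.05. The Wald score deposited by the authors had the opposite sign to the log2 fold change in all 32190 genes and was not used. The p-value deposited by the authors was missing for 148 genes and the adjusted p-value for 5086.

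Depth was read from the RPKM steps. Within a gene, RPKM values under 0.5 are whole multiples of the value of a single read, and combined with the authors' mean signal they gave whole reads in 99.98% of the values above 0, within a tolerance of 0.05 reads. A test of this step on simulated values for 31827 genes recovered 100% of them. Recovered totals ran from 13688629 to 15583776 reads per library. A gene with no read in any WT library was given a floor of 3 reads over the WT libraries together, which covers counting error only.

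Values were tested as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (linear models, empirical Bayes with an intensity trend), on the 24380 genes with an RPKM of 0.5 or more in at least 3 of the 6 libraries, without covariates. Fold changes on this scale understate those of genes with low RPKM. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

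On simulated values with the spread of the real libraries for the comparison of osnat10 with WT, the limma step over 24380 genes called 13 of 67 genes changed 2-fold (19.4%), 51 of 67 changed 4-fold (76.1%) and 61 of 66 changed 8-fold (92.4%), and 20 unchanged genes. The changed genes were drawn only from those with a mean log2(RPKM + 0.5) above 1 and were shifted on that scale. The shares called therefore do not cover genes of low RPKM. The gene list test called the 1 simulated list that had been moved and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, so this did not check false calls of lists whose members vary together. In the real values the estimated correlation between members was 0.37 for cytosolic ribosomal proteins.

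Gene lists were fixed as word patterns on symbols and descriptions. They were tested with camera of limma (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), with camera and an estimated correlation, and with fry, which tests a list against no change and not against other genes. Of 32 lists, 31 had at least 5 tested members. They cover light-harvesting proteins, photosystem subunits, photosynthetic electron transport, the Calvin cycle, photorespiration, chlorophyll synthesis, carotenoid synthesis, starch and sucrose, plastid and cytosolic ribosomal proteins, ribosome biogenesis, tRNA synthetases, translation factors, chaperones, defence, peroxidases and antioxidant enzymes, auxin, jasmonate, abscisic acid and dehydration, ethylene, cytokinin and gibberellin, the circadian clock, the cell wall, the cell cycle and histones, nutrient transport, root markers, epidermis and vascular markers, seed storage, plastid-encoded genes, pentatricopeptide proteins and transposons. The list for OsNAT10 itself matched no description, so the targeted gene was not analysed here and does not check the labels. The clock pattern also took 25 efflux, influx and POLLUX genes among its 48 tested members, and the seed storage pattern took lipid transfer proteins that share an annotated domain with seed proteins. The Calvin cycle pattern took a glycolate oxidase and Rubisco-binding chaperonins, which are not Calvin cycle enzymes. The ribosome biogenesis pattern took small nucleolar RNA genes such as snoR134, and the ethylene pattern took the sterol methyltransferase gene Ossmt2-1 by part of a word.

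Genes to be named were chosen by a rule: the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change that had an informative annotation, a mean RPKM of at least 5 in the higher group and no overlap between the groups (5 genes met this among the lower ones), and from each list the 3 members with the smallest adjusted p, or 4 in the light-harvesting, photosystem, electron transport and Calvin cycle lists. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined. Alternatives were a replicate block, no filter and a filter at an RPKM of 2, leaving out each library in turn, pseudocounts of 0.1 and 1, quantile normalisation, median of ratios scaling, robust empirical Bayes, and, for lists, an estimated correlation, median of ratios scaling and members with a mean RPKM of 5 or more. A fit with voom of limma to the recovered reads and a clock list without the efflux, influx and POLLUX members were added after the data had been seen. Gene positions in the genome were not used here, and chromosomes were read from the locus identifiers.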

Results

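RNA abundance was compared between WT and osnat10 rice seedlings, with 3 RNA-seq libraries per genotype. OsNAT10 is the rice counterpart of the enzyme that acetylates cytidine in RNA to ac4C, and the study's title links it to photosynthesis. Recovered depth was similar in the libraries. WT libraries held 13688629, 14816018 and 15583776 reads over genes, and osnat10 libraries held 13770857, 14282612 and 14857980. Between 28577 and 29464 genes had at least 1 read. The 10 most abundant genes took 6.61% of the reads in WT replicate 1, 4.51% and 3.23% in WT replicates 2 and 3, and 2.72% to 3.19% in the osnat10 libraries. Across genes, the osnat10 libraries correlated with each other at r = 0.973 to 0.980 and the WT libraries at 0.902 to 0.935, while WT and osnat10 libraries correlated at 0.887 to 0.9445, so the closest pair across genotypes lay above the closest WT pair. WT values therefore carried most of the spread, with a residual SD of 0.41 to 0.51 (log2) in WT libraries and 0.23 to 0.26 in osnat10 libraries.

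The first comparison asked which transcripts differ between osnat10 and WT. Os06g0246200, annotated as a formin-like protein of the actin-nucleating family, rose 39.6-fold in osnat10, from 0.297 ± 0.0793 to 11.8 ± 2.33 RPKM (SD, n = 3 per genotype). The GDSL lipase gene OsGELP7 rose 6.04-fold, from 11.2 ± 3.11 to 67.3 ± 1.77 RPKM, and the glucanase-family gene Gns11 rose 2.69-fold, from 45.3 ± 5.95 to 122 ± 7.64 RPKM. OsGLT2, annotated as an NADH-dependent glutamate synthase of ammonium assimilation, fell 20.7-fold, from 19.9 ± 10.1 to 0.957 ± 0.501 RPKM. OsCBSX3, annotated as similar to a planthopper-induced resistance protein, fell 9.86-fold, from 115 ± 55.5 to 11.7 ± 3.92 RPKM.

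Further called genes with higher RNA in osnat10 were the papain-like protease gene Os01g0347500 (1.00 ± 0.494 RPKM in WT and 9.96 ± 3.39 in osnat10), Os03g0628800, annotated as similar to H1flk (6.47 ± 1.00 and 18.0 ± 1.17), Os09g0433800, similar to a senescence-associated protein (13.7 ± 2.57 and 35.2 ± 1.84), the beta-expansin gene OsEXPB11, whose protein family loosens cell walls (7.64 ± 0.157 and 20.2 ± 2.68), and the homeodomain-leucine zipper gene Oshox2 (10.8 ± 0.650 and 25.3 ± 1.70). Lower in osnat10 were Os12g0169600, annotated as similar to fructose-bisphosphate aldolase with no compartment given (35.4 ± 7.0 and 7.45 ± 2.21), the EF-hand gene Os09g0115900 (32.7 ± 4.96 and 7.40 ± 0.565) and OsC3H54 (19.4 ± 1.70 and 5.35 ± 1.19). Os03g0299700, a gene of no annotated function that was chosen after its values were seen, had no read in any WT library and 1473 recovered reads in osnat10 (20.9 ± 2.13 RPKM), at least 507-fold higher against a floor of 3 reads over the WT libraries.

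**Figure D1:**
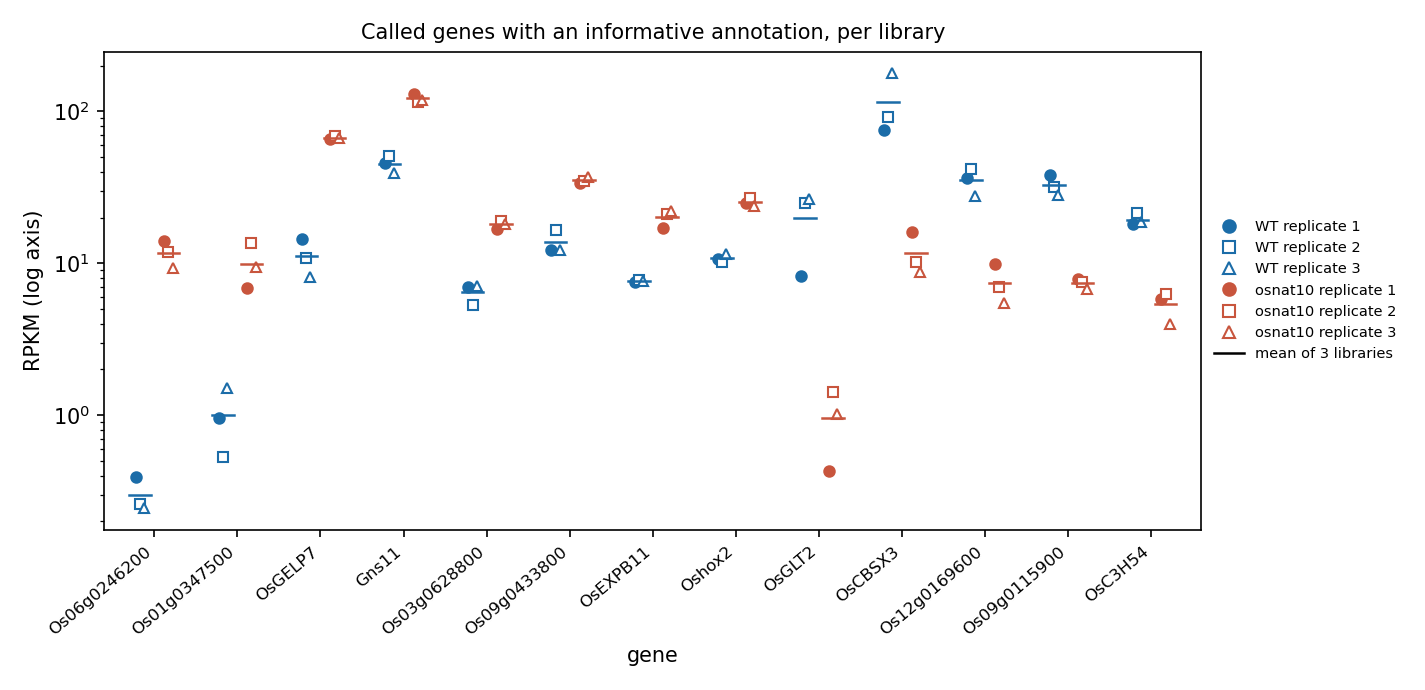
RPKM (log axis) of the 13 called and annotated genes in each of the 3 WT libraries (blue) and 3 osnat10 libraries (red), with lines at the means. The osnat10 points lie apart from the WT points in every gene, and the widest separations are at Os06g0246200 (log2 fold change 3.93) and OsGLT2 (log2 fold change -3.70).

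In limma, 30 genes were higher and 7 lower in osnat10, all by 2-fold or more, and 4693 of the 24380 tested genes had an unadjusted p under 0.05. Among the 13 named genes the log2 fold change ran from 3.93 (SE 0.25, adjusted p = 0.0018) for Os06g0246200 to -3.70 (SE 0.48, adjusted p = 0.048) for OsGLT2. The median log2 fold change over all genes was 0.11, and it was 0.01 under median of ratios scaling and -0.03 after quantile normalisation. The share of higher genes moved with the scaling, with 30 of 37 calls (81.1%) higher as deposited, 51 higher and 57 lower (47.2% higher) under median of ratios scaling, and 28 higher and 24 lower (53.9% higher) after quantile normalisation.

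The number of calls depended on single libraries. Without WT replicate 1, limma called 1532 genes higher and 1181 lower, and without WT replicate 3 it called 886 and 99. Without WT replicate 2 it called 10 and 0, and without osnat10 replicates 1, 2 and 3 it called 8 and 0, 10 and 1, and 10 and 0, with 2617 to 7025 genes at an unadjusted p under 0.05 in these 6 fits. All 37 genes were called again without WT replicate 1 and without WT replicate 3. Of the 13 named genes, 1 (Os06g0246200) was called without WT replicate 2 and without each osnat10 replicate, where adjusted p of the 13 genes reached 0.154 to 0.316.

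Among groups of genes, cytosolic ribosomal proteins, the building blocks of the ribosomes in the cytoplasm, rose as a list in osnat10. Of 158 such genes, 147 had a positive log2 fold change, and the list's median lay 0.38 (log2) above the median of all genes (camera adjusted p = 4.7e-19). The adjusted p = 0.69 with an estimated correlation, and fry, which tests a list against no change, gave an adjusted p of 0.024. Over all genes 0 of the 158 were called, while limma adjusted over the list alone called 82 higher and 2 lower. The ubiquitin-ribosomal fusion gene Ub-CEP52-2 stood at 14.3 ± 3.09 RPKM in WT and 42.9 ± 9.15 in osnat10 (log2 fold change 1.55, SE 0.23, adjusted p = 0.055). The S11 gene Os08g0207000 stood at 37.4 ± 5.51 and 87.1 ± 12.3 RPKM (adjusted p = 0.055), and RPS10 at 29.3 ± 3.79 and 60.3 ± 5.20 RPKM (adjusted p = 0.057). Plastid ribosomal proteins did not pass as a list (19 genes, median 0.01 below that of all genes, camera adjusted p = 0.82). One of them, the plastid-specific ribosomal protein gene Os03g0856500, stood at 796 ± 318 RPKM in WT and 173 ± 11.9 in osnat10 (log2 fold change -2.10, adjusted p = 0.058, and 0.00074 without WT replicate 1, with a range of 0.00074 to 0.32 over the alternatives). WT replicates 1, 2 and 3 held 432.7, 1019 and 936.7 RPKM of Os03g0856500. The fit without WT replicate 1 thus keeps only its higher WT values and does not separate genotype from the difference within WT.

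Cell wall genes rose as a list in osnat10, with 161 of 193 log2 fold changes positive and a median 0.51 above that of all genes (camera adjusted p = 9.7e-07, and adjusted p = 0.20 with an estimated correlation), and fry gave an adjusted p of 0.014. With no filter the median lay 0.31 above that of all genes. Called over all genes was 1 member, OsEXPB11, and limma adjusted over the list alone called 30 higher and 2 lower. OsEXPB7, another expansin, stood at 7.24 ± 3.30 RPKM in WT and 27.3 ± 7.78 in osnat10 (adjusted p = 0.071), and the cellulose synthase gene OsCesA6 at 46.7 ± 6.83 and 89.6 ± 8.23 RPKM (adjusted p = 0.076). Cell cycle and histone genes lay higher than other genes as a list (69 of 80 positive, median 0.40 above that of all genes, camera adjusted p = 1.7e-05), with an adjusted p = 0.86 with an estimated correlation and 0.17 in fry. No member was called in limma, over all genes or adjusted over the list alone. The list's median log2 value above the library median was 1.406 in osnat10 replicate 2, within the WT values of 1.356, 1.417 and 1.119. It was 1.935 and 1.842 in osnat10 replicates 1 and 3. The histone H2A gene Os12g0438000 stood at 31.0 ± 6.07 and 56.1 ± 5.68 RPKM, the mitotic checkpoint kinase gene Os02g0193600 at 4.66 ± 1.13 and 9.72 ± 1.14, and MAD2 of the spindle checkpoint at 6.15 ± 1.38 and 13.5 ± 3.54.

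Peroxidases and antioxidant enzymes rose as a list (125 of 177 positive, median 0.33 above that of all genes, camera adjusted p = 0.019, and adjusted p = 0.59 with an estimated correlation), and fry gave an adjusted p of 0.024. The median lay 0.22 above that of all genes without WT replicate 3 and 0.20 with no filter. Over all genes 0 were called, and limma adjusted over the list alone called 35 higher and 9 lower. The peroxidase gene prx127 stood at 0.797 ± 0.861 RPKM in WT and 10.9 ± 2.27 in osnat10, prx83 at 5.82 ± 2.07 and 17.1 ± 0.944, and prx27 at 18.6 ± 4.6 and 45.4 ± 3.86 (adjusted p = 0.055, 0.062 and 0.062).

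Root markers lay higher than other genes as a list of 10 genes (8 positive, median 1.26 above that of all genes, camera adjusted p = 0.023, and adjusted p = 0.69 with an estimated correlation), with an adjusted p of 0.091 in fry. Over all genes 0 were called, and limma adjusted over the list alone called 6 higher and 0 lower. The list's camera adjusted p was 0.051 without WT replicate 3 and 0.059 without osnat10 replicate 3. Most of the positive members were genes for RCc-type root proteins, with RCc3 at 224 ± 108 RPKM in WT and 590 ± 69.2 in osnat10 and RCc2 at 26.9 ± 8.49 and 73.3 ± 20.5. The silicon channel gene LSI6 stood at 13.5 ± 4.38 and 32.8 ± 3.18 RPKM. The 2 negative members, chosen for naming after their values were seen, were the root silicon transporter genes LSI1 (214 ± 67.0 and 166 ± 20.4 RPKM, adjusted p = 0.49) and LSI2 (130 ± 45.2 and 104 ± 19.5 RPKM, adjusted p = 0.60).

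Seed storage genes rose as a list (30 of 39 positive, median 0.36 above that of all genes, camera adjusted p = 0.023, and adjusted p = 0.42 with an estimated correlation), and fry gave an adjusted p of 0.014. OsAGP29, annotated with a domain shared by lipid transfer and seed storage proteins, was the 1 member called over all genes (0.104 ± 0.102 RPKM in WT and 1.94 ± 0.349 in osnat10, adjusted p = 0.048), and limma adjusted over the list alone called 4 higher and 0 lower. The glutelin-family gene Os01g0644600 stood at 18.4 ± 2.10 and 35.4 ± 6.14 RPKM and OsLTPd2 at 18.8 ± 7.36 and 51.0 ± 3.60 RPKM. The list's median log2 value above the library median was 0.515, 0.845 and 0.809 in the WT libraries and 0.57, 0.82 and 0.80 in the osnat10 libraries. On that measure the genotypes overlapped. With the stricter filter the list's camera adjusted p was 0.069, and the median lay 0.23 above that of all genes without WT replicate 2, 0.21 without osnat10 replicate 2 and 0.22 with no filter.

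The second question was whether photosynthesis genes differ. Photosystem subunit, Calvin cycle and carotenoid synthesis genes lay slightly below other genes as lists, and no member of these lists was called over all genes. Against no change, fry gave an adjusted p of 0.77, 0.61 and 0.62 for these lists, so a fall of the lists themselves was not shown. Photosystem subunits (49 genes, 27 negative) had a median 0.17 below that of all genes (camera adjusted p = 0.029, and adjusted p = 0.86 with an estimated correlation), while their mean log2 fold change was 0.02 and their median -0.06. Calvin cycle genes (18 of 24 negative) had a median 0.36 below that of all genes (camera adjusted p = 0.038, and adjusted p = 0.86 with an estimated correlation). Carotenoid synthesis genes (16 of 30 negative) had a median 0.18 below that of all genes (camera adjusted p = 0.024, and adjusted p = 0.86 with an estimated correlation). Adjusted over the list alone, limma called 3 members of the photosystem list lower, all of PsbP or PsbQ annotation, and 1 higher, Os03g0157900, which is annotated as a phosphoserine aminotransferase of serine synthesis and was taken by its abbreviation PSAT, and 0 Calvin cycle and 0 carotenoid synthesis genes.

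Among single photosynthesis genes, OsLFNR2, which encodes the leaf ferredoxin-NADP reductase at the end of the electron transport chain, stood at 329 ± 67.8 RPKM in WT and 153 ± 16.7 in osnat10 (log2 fold change -1.09, SE 0.21, adjusted p = 0.081). LIR1, which anchors that reductase to the thylakoid, stood at 1138 ± 421 and 334 ± 62.5 RPKM (log2 fold change -1.70, SE 0.34, adjusted p = 0.085). WT replicates 1, 2 and 3 held 657.5, 1440 and 1317 RPKM of LIR1. Its limma adjusted p was 0.0040 without WT replicate 1, with a range of 0.0040 to 0.38 over the alternatives. The fit without WT replicate 1 keeps only the higher WT values, of WT replicates 2 and 3. Its smaller p therefore does not separate genotype from the difference within WT. The electron transport list of 9 genes had a median 0.33 below that of all genes (camera adjusted p = 0.055), and limma adjusted over the list alone called 1 higher and 2 lower. The higher one was FNR, annotated as the root isozyme (47.6 ± 16.7 and 81.0 ± 6.9 RPKM, limma adjusted p = 0.16 over all genes). In the photosystem list, the PsbP-family gene Os08g0504500 stood at 68.2 ± 7.61 and 40.9 ± 3.75 RPKM (adjusted p = 0.093) and the PsbQ-family gene Os07g0105600 at 215 ± 25.1 and 129 ± 16.3 RPKM (adjusted p = 0.11). In the Calvin cycle list, taken by annotation, the glycolate oxidase gene OsGLO1 stood at 338 ± 61.2 and 208 ± 29.2 RPKM (adjusted p = 0.15). The Rubisco small subunit gene RbcS3, chosen after its values were seen, stood at 2724 ± 565 and 2607 ± 345 RPKM (adjusted p = 0.95). OsLCYe, a lycopene cyclase gene of carotenoid synthesis, stood at 44.6 ± 5.75 and 27.0 ± 1.98 RPKM (adjusted p = 0.099).

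The photosynthesis lists differed between WT replicate 1 and WT replicates 2 and 3. Relative to the library medians, light-harvesting genes were 3.79 (log2) higher in WT replicate 1 than in WT replicates 2 and 3, photosystem subunits 1.15, electron transport genes 0.97, carotenoid synthesis genes 0.70 and Calvin cycle genes 0.62. The photosystem list shares 5 tested members with the light-harvesting list, and its other 44 genes were 0.98 higher in WT replicate 1. Cytosolic ribosomal protein, cell wall and histone genes differed there by 0.10, 0.13 and 0.11, and root markers by 0.93. Peroxidases and antioxidant enzymes were 0.34 higher in WT replicate 1 than in WT replicates 2 and 3, near the 0.38 by which osnat10 lay above those 2 libraries. Without WT replicate 1 the camera adjusted p was 0.053 for photosystem subunits, whose median then lay 0.20 above that of all genes, 0.73 for the Calvin cycle (median -0.069 relative to all genes) and 0.82 for carotenoid synthesis (-0.029). Without WT replicate 3 the relative medians were -0.40 for photosystem subunits, -0.54 for the Calvin cycle and -0.27 for carotenoid synthesis, and without WT replicate 2 they were -0.30 for photosystem subunits and -0.28 for carotenoid synthesis. These lists also lost their calls without osnat10 replicate 3 (0.072, 0.072 and 0.059), and photosystem subunits and the Calvin cycle without osnat10 replicate 1 (0.11 and 0.0997). With the stricter filter, 0 lists were called lower in camera.

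Light-harvesting genes, which encode the chlorophyll-binding antenna, differed more within WT than between genotypes. CAB1R stood at 1064 RPKM in WT replicate 1, at 5.10 and 10.9 in WT replicates 2 and 3, and at 337, 363 and 428 in the osnat10 libraries. CAB2R stood at 1992, 22.3 and 24.8 RPKM in WT and at 665, 477 and 641 in osnat10. The list of 16 genes had a median 0.64 above that of all genes and did not pass (camera adjusted p = 0.59), and limma called 0 members over all genes or adjusted over the list alone. Without WT replicate 1 its median lay 1.95 above that of all genes (camera adjusted p = 2.6e-11), without WT replicate 2 it lay 0.23 above (camera adjusted p = 0.60), and without WT replicate 3 it lay at -0.037 (camera adjusted p = 0.41). The clock genes CCA1 and LHY, chosen after their values were seen, followed the same order, with CCA1 at 162, 3.71 and 2.52 RPKM in the WT libraries and 62.3, 50.3 and 50.9 in osnat10, and LHY at 40.3, 4.25 and 3.30 in WT and 19.8, 16.4 and 20.04 in osnat10.

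**Figure D2:**
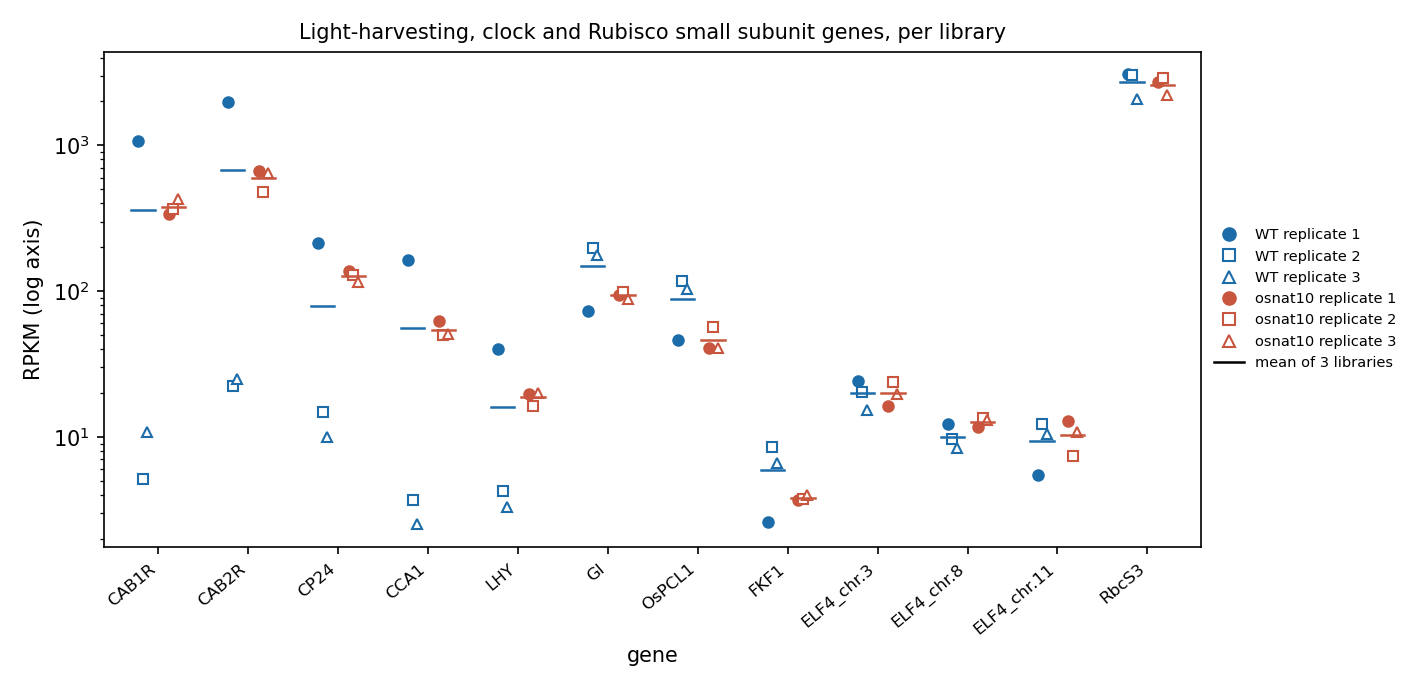
RPKM (log axis) of light-harvesting (CAB1R, CAB2R, CP24), clock (CCA1 to ELF4_chr.11) and Rubisco small subunit (RbcS3) genes in each of 3 WT libraries (blue) and 3 osnat10 libraries (red), with lines at the means. At CAB1R, WT replicate 1 (1064 RPKM) and WT replicates 2 and 3 (5.10 and 10.9) lie on opposite sides of the osnat10 libraries (337 to 428), while RbcS3 differs little.

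**Figure D3:**
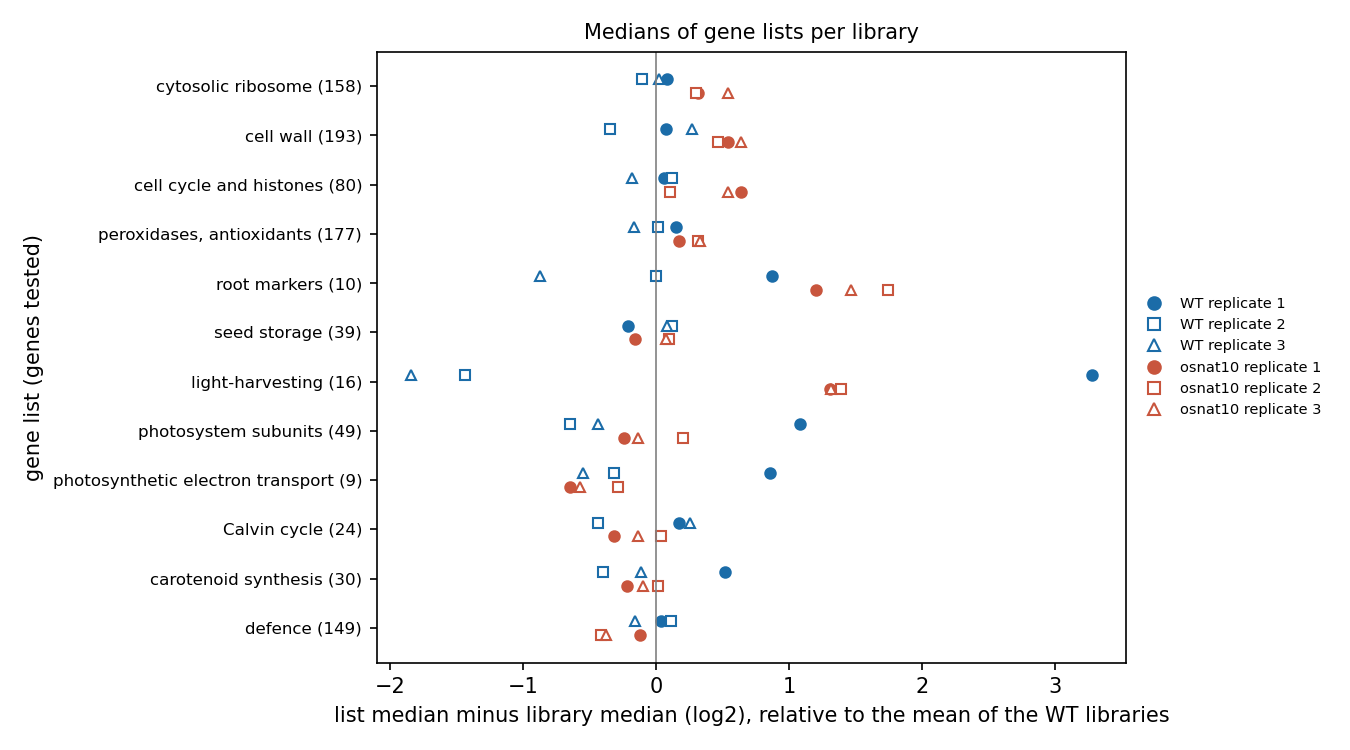
Median log2(RPKM + 0.5) of 12 gene lists in each library, minus the library's median over all tested genes and relative to the mean of the WT libraries. Ribosomal protein and cell wall medians of the osnat10 libraries (red) lie above all WT medians (blue), and the light-harvesting medians of WT replicates 1, 2 and 3 (6.98, 2.26 and 1.86 above the library medians) lie on both sides of those of osnat10 (5.01 to 5.09). Medians of seed storage, cell cycle and histone, electron transport, Calvin cycle, carotenoid synthesis and defence genes overlap between the genotypes. Photosystem medians of osnat10 (3.492 to 3.935) lie between those of WT replicate 1 (4.816) and of WT replicates 2 and 3 (3.084 and 3.293).

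The remaining lists of this part did not pass. Photorespiration genes (16) had a median 0.21 below that of all genes and a mean log2 fold change of 0.0074 (camera adjusted p = 0.69), and limma adjusted over the list alone called 4 higher and 2 lower, among the former the glycine cleavage H-protein gene Os02g0170100 (52.0 ± 10.3 and 103 ± 9.52 RPKM, adjusted p = 0.081 over all genes). Chlorophyll synthesis genes (25) had a median 0.12 above that of all genes (camera adjusted p = 0.82), with OsPorA, a protochlorophyllide reductase gene, at 10.4 ± 6.93 and 48.2 ± 11.2 RPKM (adjusted p = 0.10). Starch and sucrose genes (58) had a median 0.07 above that of all genes (camera adjusted p = 0.79), and limma adjusted over the list alone called 0 higher and 2 lower. The sucrose synthase gene SUS4 stood at 32.2 ± 14.9 and 8.05 ± 0.719 RPKM (adjusted p = 0.085). Of 54 plastid-encoded genes matched, only 5 passed the filter, so they do not stand for the plastid genome. These 5 were all negative (median 0.82 below that of all genes, camera adjusted p = 0.055), at low RPKM such as 2.08 ± 0.583 and 1.07 ± 0.337 for psbK. That gene had 22 recovered reads in WT and 11 in osnat10.

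Defence genes lay slightly below other genes as a list (79 of 149 negative, median 0.16 below that of all genes, camera adjusted p = 0.031, and adjusted p = 0.86 with an estimated correlation), with an adjusted p of 0.84 in fry against no change. Over all genes 0 were called, and limma adjusted over the list alone called 4 higher and 3 lower. The chitinase gene Os10g0543400 stood at 4.81 ± 1.58 RPKM in WT and 0.860 ± 0.302 in osnat10 (adjusted p = 0.060), while the pathogenesis-related gene PR1A stood at 23.4 ± 11.8 and 67.99 ± 14.1 RPKM (adjusted p = 0.088). The list's camera adjusted p was 0.053 without WT replicate 1 and 0.12 without osnat10 replicate 2, and its median lay 0.086 below that of all genes without WT replicate 2. None of the list calls was kept with an estimated correlation, where the smallest adjusted p was 0.20, for the cell wall list. Lower list calls numbered 4, and 1, 7 and 1 without WT replicate 1, WT replicate 2 and osnat10 replicate 3.

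The authors' deposited table called 655 genes higher and 1026 lower in osnat10 at an adjusted p under 0.05. All 37 genes called by limma were called in the same direction in the authors' deposited table. Both comparisons drew on the same RNA-seq libraries, so their accord is not independent evidence. Of its 1681 genes, 1602 were tested here, and 1547 of these had an unadjusted limma p under 0.05 in the same direction as in the authors' deposited table. Across genes, the log2 fold changes of limma and of the authors' deposited table had a Spearman rho of 0.97, with genes not being independent replicates. Cytosolic ribosomal protein genes were called 37 times higher and 1 time lower in the authors' deposited table, cell wall genes 19 and 4 times, peroxidases and antioxidant enzymes 13 and 11 times, root markers and seed storage genes 3 and 0 times each, histone and cell cycle genes 8 and 0 times, and defence genes 6 and 25 times. LIR1 had a log2 fold change of -1.84 (SE 0.30, adjusted p = 2.05e-07) and OsLFNR2 one of -1.21 (SE 0.23, adjusted p = 3.8e-05) in the authors' deposited table. Of the 16 light-harvesting genes, 9 had no adjusted p in the authors' deposited table and 0 of the others were called.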

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

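The voom fit to recovered reads and the clock list without efflux, influx and POLLUX members were chosen after the data had been seen. Leaving out single libraries moved the calls from 30 higher and 7 lower to between 8 and 1532 higher and between 0 and 1181 lower, and the lists called lower from 4 to between 1 and 7, with fewer samples in each fit. Higher and lower genes numbered 16 and 4 with the replicate block, 51 and 57 under median of ratios scaling, 19 higher with a pseudocount of 0.1, 14 higher with voom, 24 lower after quantile normalisation and 17 lower with robust empirical Bayes. With an estimated correlation 0 lists were higher and 0 lower, and lists lower numbered 0 with the stricter filter and 1 each under median of ratios scaling and with members at a mean RPKM of 5 or more. The authors' deposited table held 411 genes higher and 671 lower at 2-fold or more. The cause of these shifts was not tested.

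Deviations of libraries with the same replicate number correlated at -0.06, -0.03 and 0.13, and 2 of 6 libraries correlated best with their own number, so the numbers gave no pairing. The replicate block called 6 lists higher and 5 lower.

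Of 1730 values of the 116 named genes under the alternatives, 1524 kept direction and side of the threshold, 89 lost and 113 gained a call, and 4 changed sign, all of RbcS3 (-0.05), at 0.051, 0.035, 0.062 and 0.55 without WT replicates 1 and 2, without osnat10 replicate 3 and after quantile normalisation, with a range of -0.24 to 0.062 over the fits without one library. Relative to all genes, the photosystem median changed sign to 0.20 without WT replicate 1 (range -0.40 to 0.20 without one library) and the light-harvesting median to -0.037 without WT replicate 3 (range -0.037 to 1.95). The clock list (0.02) changed sign to -0.060 with the stricter filter, -0.15 without WT replicate 3, -0.023 without osnat10 replicate 3 (range -0.15 to 0.18 without one library), -0.046 with members at a mean RPKM of 5 or more and -0.21 without the transport genes. The cause was not tested. Apart from the voom fit to recovered reads, alternatives for counts and for acRIP-seq were not run, since the values are RPKM and the acRIP-seq libraries were not analysed here. At this depth and spread, simulated 2-fold changes were called in 19.4% of the genes changed, which left out genes of low RPKM, so 2-fold differences can go undetected. False calls in that simulation exceeded the nominal share of 0.05.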

Other observations

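Hormone and transport lists did not pass in camera. Auxin genes (142, 99 positive) had a median 0.09 above that of all genes (adjusted p = 0.23), and limma adjusted over the list alone called 2 higher. The auxin-binding protein gene Os04g0288100 stood at 10.4 ± 4.77 RPKM in WT and 49.4 ± 12.4 in osnat10 (adjusted p = 0.055), and the auxin repressor gene OsIAA3 at 28.4 ± 5.66 and 61.4 ± 6.34 RPKM (adjusted p = 0.070). Nutrient transport genes (58) had a median 0.22 above that of all genes (adjusted p = 0.30), with the nicotianamine synthase gene OsNAS1, of iron handling, at 449 ± 68.8 and 880 ± 182 RPKM and the mitochondrial phosphate carrier gene OsPT15 at 96.2 ± 12.2 and 195 ± 17.3 RPKM. Cytokinin and gibberellin genes (62, median 0.16 above, adjusted p = 0.37), jasmonate genes (51, 0.07 above, 0.65), ethylene genes (53, 0.11 below, 0.34) and abscisic acid genes (60, 0.01 above, 0.52) did not pass either. The jasmonate synthesis gene AOC stood at 48.9 ± 4.04 and 74.5 ± 2.42 RPKM (adjusted p = 0.11) and ERF130 at 14.6 ± 1.92 and 6.66 ± 1.32 RPKM (adjusted p = 0.083).

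Of the lists around protein synthesis, ribosome biogenesis (32 genes, median 0.07 above that of all genes, camera adjusted p = 0.59), translation factors (66, 0.02 below, 0.98), tRNA synthetases (50, 0.11 below, 0.074) and chaperones (182, 0.02 above, 0.98) did not pass, in contrast to the ribosomal proteins, a difference that was not tested. The ribosome biogenesis list mixes protein genes with small nucleolar RNA genes such as snoR134 (4.38 ± 1.61 and 1.82 ± 0.811 RPKM), which limits that contrast. Among chaperones, the DnaJ gene OsDjC10 stood at 7.58 ± 4.09 RPKM in WT and 0.417 ± 0.0845 in osnat10 and Os03g0656100 of the small heat shock proteins at 4.10 ± 0.759 and 12.6 ± 2.10 RPKM (adjusted p = 0.055 for both). Pentatricopeptide genes of organelle RNA processing (302, median 0.10 below, adjusted p = 0.074), transposons (42, 0.11 below, 0.58), epidermis and vascular markers (22, 0.40 above, 0.34) and the clock list (48, 0.02 above, 0.82) did not pass. For the chaperone, abscisic acid and clock lists the direction in camera was down, opposite to the sign of the median relative to all genes, and for translation factors it was up, also opposite to that sign. CMT2, a DNA methyltransferase gene of transposon silencing, stood at 6.74 ± 1.81 and 14.0 ± 2.56 RPKM (adjusted p = 0.11).

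The tests on afternoon and evening clock genes, on scaling and on other splits of the libraries were set before their results were seen, and those on a wrong label, green shoot, root share, a linked segment and missing genes were chosen after.

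Light-harvesting and dawn clock genes stood far higher in WT replicate 1 than in WT replicates 2 and 3 (CCA1 52.1-fold), with osnat10 between. Over the 24380 tested genes, WT replicate 1 minus WT replicate 2 correlated with mean osnat10 minus WT replicate 3 at r = 0.51. With WT replicates 2 and 3 exchanged, r was 0.15. For the 16 light-harvesting genes these values were 0.96 and 0.93. Differences between the genotypes may thus carry the same pattern, which was not tested for single genes. A larger share of green shoot in WT replicate 1 is argued against as the only source of the light-harvesting difference. Calvin cycle genes differed there by 0.62 (log2) and light-harvesting genes by 3.79. A partial share is not excluded, since photosystem (1.15), electron transport (0.97) and plastid ribosomal protein genes (0.94) were also higher there. Cytosolic ribosomal protein genes differed by 0.10, but root markers were higher too, by 0.93. A mislabelled osnat10 library met the bound first set for it: at 183 genes at least 4-fold apart between osnat10 and WT replicates 2 and 3, WT replicate 1 lay nearer the WT side at 36 (19.7%), just under the bound of 20%. It is nevertheless argued against by checks added once that share was seen, since the same share was 0.943% to 2.98% for each osnat10 library held out, and 22 genes stood at least 4-fold apart between all WT and all osnat10 libraries, against at most 2 in other splits. Harvest at another time of day may explain the pattern, since the afternoon and evening genes OsPCL1, FKF1 and ELF4_chr.11 were lower in WT replicate 1 by -1.23, -1.37 and -0.99 (median of 5 genes -0.99), although ELF4_chr.3 and ELF4_chr.8 were 0.44 and 0.42 higher, and the labels give no harvest time.

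Of these 22 genes, 20 were higher in osnat10 and 2 lower (OsGLT2 and OsCBSX3), and 13 had no informative annotation. One linked segment carried along with the mutation is argued against for the set as a whole, since the 22 genes lie on 11 chromosomes with at most 5 on one, chromosome 7. Genes missing from the WT genome are argued against for 5 of the 20 genes higher in osnat10, which had at least 10 recovered reads in every WT library, apart from reads shared with near-identical or overlapping genes. For the other 15, that minimum was not met, so it does not tell absence from low expression. Of these, 3 (Os03g0299700, Os04g0397800 and Os07g0560400) had no read in any WT library and the other 12 had under 10 in at least 1 WT library. The 12 were not all near 0. OsLTP1.2 had 81 WT reads, at 0.14, 2.6 and 2.3 RPKM in WT replicates 1, 2 and 3, and reads shared with similar genes cannot be excluded. A difference caused by the mutation remains open for all 22, as a hypothesis.

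Cytosolic ribosomal protein, cell wall, and cell cycle and histone genes stood higher than other genes in osnat10. The test on scaling between the libraries could not decide this. A scaling factor per library moves all genes nearly alike and leaves their standing relative to other genes in place. Under median of ratios scaling the 431 genes of the 3 lists had a median log2 fold change of 0.42, and the median of all genes was 0.01. A larger share of root in osnat10 cannot be told apart from a change within tissues: the 10 root markers had a median log2 fold change of 1.36, but the abundant root transporters LSI1 and LSI2 had a mean of -0.31 (SE 0.18). That SE takes the 2 genes as independent, although both were highest in WT replicate 2 (291.1 and 181.2 RPKM), so it may be too small. The bound first set for those transporters, which uses that SE, was met on the side against a root share. The other 8 markers were counted as well only after that was seen. An effect of genotype on these lists remains open as a hypothesis.

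Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one (37, itself), with 0 as the highest of the others, and 10 splits are too few for a share under 0.05. For the lists, 8 of the 10 splits gave at least the 10 calls of the real split, and the highest of the others gave 13, so the number of list calls does not set the genotypes apart from other splits.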
